A study of Cercospora zeina with 7 samples.

How the data were processed

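RNA sequencing libraries were made from 7 cultures of Cercospora zeina strain CMW25467, a fungus that causes grey leaf spot of maize, with 1 library per culture medium. Per the labels' protocols, mycelium was lifted from cellophane on plates or filtered out of liquid medium, frozen and ground, and total RNA was extracted with QIAzol, treated with DNase on column and made into Illumina libraries by a sequencing service. The protocols do not say which of the media were liquid, apart from what the names agar and broth tell.

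The deposited files hold whole-number read counts per gene model, 1 file per library, with totals that differ between libraries, and were used as raw counts. Per the submitters' processing notes, FastQC, TopHat2, SAMtools and HTSeq were used. Their versions, the genome build, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Reads of overlapping or antisense gene models, and of near-identical copies, can therefore not be assigned with certainty from these counts. Each file listed the same 10130 gene models under protein identifiers, and no row held unassigned reads. The files do not pair these identifiers with gene names or positions (the letters PKR and PKS are prefixes of the identifiers, not gene names), and no genome or annotation was used here. The 35 gene lists fixed beforehand (pathways by product name, protein motifs) could not be applied, and 0 of them were matched to the gene models.

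From the counts, CPM (the reads of a gene model scaled to a common library total) were computed with effective library sizes from the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. TMM sets each library's scale from the bulk of gene models that differ little between libraries. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Fold differences were taken on the CPM + 1 scale, which understates the difference of low genes. A gene model was called elevated in a medium when it had at least 50 reads there and lay at least 4-fold above the highest of the other 6 media. It was called lowered when it lay at least 4-fold below the lowest of the other 6 media and had at least 50 reads in each of them. The pairs PDB-pH3 with PDA-pH8 and PDA-AP with PDA-pH8 were compared by the same 4-fold rule, with at least 50 reads in the higher library. Detection meant at least 10 reads. These rules, the alternatives and the rule for naming gene models were fixed before the data were examined.

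With 1 library per medium no spread between replicates exists, so no test between media was run and no p-value is given. The 95% intervals printed beside ratios are exact conditional binomial intervals, and those beside shares of reads are exact Clopper-Pearson intervals. Both cover counting error of reads only, not variation between cultures. The reads carry no molecular identifiers, so duplicate reads of a molecule were counted as separate reads. The libraries' totals of 20211530 to 21599254 gene-assigned reads make a count of 3 reads worth 0.139 to 0.148 CPM before TMM. For each of 3 comparisons, at most 2 identifiers higher and 2 lower were named, those with the largest ratio on the CPM + 1 scale; the 7 comparisons of one medium against the others were taken as a single family. The ratios printed beside named gene models are of CPM without the pseudocount.

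The calling rules were tested on simulated counts for all 10130 gene models with 200 changed genes per simulation, 50 each at 2, 3, 6 and 10-fold, drawn from gene models with at least 1000 expected reads, so that the recovery of weakly expressed genes was not tested. All simulated media shared one baseline, the mean level of each gene model over the media, so real differences among the other media were not simulated. The rates below therefore need not hold in these libraries, above all for one medium against the other 6. For each of the 3 kinds of comparison, with counting error alone, 100% of the genes changed 6-fold and 10-fold were recovered, 0% of those changed 2-fold or 3-fold were called, and 0 unchanged genes were called. With an assumed coefficient of variation of 0.3 between cultures, 46% of the genes raised 6-fold in YPD-media were recovered against the other 6 media, and 0 unchanged genes were called. For PDB-pH3 against PDA-pH8 at the same variation, 84% of the genes raised 6-fold were recovered, 26% of those raised 3-fold and 28% of those lowered 3-fold were called although under the threshold, and 10 unchanged genes were called higher and 3 lower. For PDA-AP against PDA-pH8, 72% of the genes raised and 80% of those lowered 6-fold were recovered, 26% and 24% of the 3-fold genes were called, and 6 unchanged genes were called higher and 4 lower. The alternatives were DESeq2 1.42.0 median-of-ratios size factors, scaling by total reads, other read minimums, a pseudocount of 5 CPM, thresholds of 2-fold and 8-fold, the median of the other media as reference, thinning to equal depth, and other filters and coefficients for the correlations. Leaving YPD-media out was added after seeing the data.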

Results

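Transcripts of C. zeina mycelium were counted after growth in 7 culture media, with 1 library for each medium and no biological replicates. The media were labelled Complete-media, Cornmeal-agar, PDA-AP, PDA-pH8, PDB-pH3, V8-media and YPD-media. PDA and PDB are the usual short names of potato dextrose agar and broth, YPD is a rich medium of yeast extract, peptone and dextrose, and V8 is based on vegetable juice. The label does not spell out AP. The libraries held 20211530 (PDA-AP) to 21599254 (PDB-pH3) reads assigned to 10130 gene models, so depth differed little between media. The series was made to annotate gene models, and the first question was how many models had transcripts in culture.

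Most gene models were transcribed in every medium. At least 10 reads were counted for 9420 gene models (93.0%) in at least 1 medium and for 8727 (86.2%) in all 7. Another 693 gene models reached 10 reads in 1 to 6 media, and 77 did so in exactly 1 medium, of which 36 were in YPD-media, 14 in PDA-AP and 13 in Complete-media. No read was counted in any library for 588 gene models (5.8%), and 122 had reads but fewer than 10 in every library. With a minimum of 1 read in place of 10, 261 gene models were detected in 1 to 6 media and 16 in exactly 1, and with a minimum of 1 CPM 134 were detected in exactly 1. A count of 0 in 1 library allows up to 0.139 to 0.148 CPM before TMM, depending on the library's total.

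Single media detected between 8988 (V8-media) and 9275 (Complete-media) gene models. The gain from further media was small. The best pair, Complete-media with YPD-media, covered 9371 gene models, and the best set of 3, which added PDA-AP, covered 9400 of the 9420. V8-media, YPD-media and PDB-pH3 were most often the single medium in which a gene model was missed, with 80, 74 and 57 gene models that reached 10 reads in each of the other 6 media. Complete-media and Cornmeal-agar missed 4 and 3 gene models in this way.

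The gene models with the most reads, called most abundant here, differed between media. Reads were not divided by gene length, which was not available, so these ranks favour long gene models. The union of the 100 most abundant gene models of each library held 270 gene models, of which 19 were in the top 100 of all 7 media. YPD-media had 44 and V8-media 33 of their top 100 in no other medium's top 100, against 3 for Cornmeal-agar. The gene model with the highest mean level took 3.54% of the reads in PDB-pH3. Its normalised read count was 43940 CPM there and 1322 CPM in V8-media, a 33.2-fold range.

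The 10 most abundant gene models of each library held 6.93% of the reads in YPD-media (95% Clopper-Pearson interval 6.92 to 6.94), 7.61% in PDA-pH8, 8.44% in Complete-media, 9.43% in V8-media, 10.13% in Cornmeal-agar, 11.69% in PDA-AP and 13.1% in PDB-pH3 (13.08 to 13.11). The top 100 held from 23.71% in YPD-media to 34.27% in PDB-pH3. At the other extreme, 5717 gene models lay at 10 CPM or more in all 7 media, and 1321 of these (23.1%) varied by less than 2-fold from the lowest to the highest medium. The median range of these 5717 was 2.87-fold, and 397 of them varied 10-fold or more. A further group of 222 gene models reached 10 CPM in at least 1 medium and lay under 1 CPM in another. The lowest value of these was in V8-media for 79 and in YPD-media for 68, and the highest was in Complete-media for 66.

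Expression profiles were next compared between the media across the 9420 detected gene models, which are not independent replicates. YPD-media stood apart from all other media. Its Spearman rho with the others ran from 0.774 (Complete-media) to 0.846 (PDB-pH3), whereas the 15 pairs without YPD-media ranged from 0.861 to 0.963. Cornmeal-agar and PDA-AP were the closest pair (rho = 0.963, Pearson r = 0.964), followed by Complete-media with PDA-pH8 (0.949) and Complete-media with Cornmeal-agar (0.946). The 2 cultures on PDA were less alike (0.896) than PDA-AP and Cornmeal-agar. In a principal component analysis of the centred log2 values, the first component held 41.4% of the variance with a weight of 0.86 on YPD-media. The second (22.5%) had its largest weight on V8-media (0.81), and the third (15.2%) on PDB-pH3 (0.81).

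**Figure D1:**
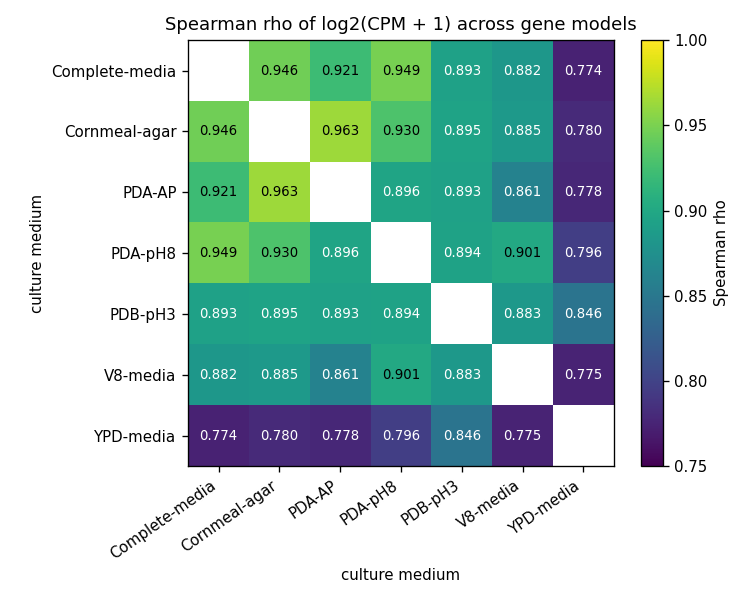
Matrix of Spearman rho between the 7 media (both axes), from log2(CPM + 1) of 9420 gene models, with colour and printed value giving rho for each pair of single libraries. The YPD-media row holds the lowest values, 0.774 to 0.846, and Cornmeal-agar with PDA-AP the highest, 0.963.

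Gene models set apart in a single medium were found most often in YPD-media. There, 197 gene models lay at least 4-fold above the highest of the other 6 media, and 101 lay at least 4-fold below the lowest. V8-media followed with 52 elevated and 25 lowered gene models, and PDB-pH3 with 34 and 3. PDA-pH8 had 21 elevated and 2 lowered, Complete-media 19 and 1, PDA-AP 18 and 2, and Cornmeal-agar 1 and 0. YPD-media thus held 57.6% of the 342 elevated and 75.4% of the 134 lowered calls over all media. With the median of the other 6 media as the reference, it held 34.3% of 1734 elevated and 53.8% of 945 lowered calls, and V8-media, with 190 elevated, came after PDB-pH3 (263), PDA-AP (207) and Complete-media (202).

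The 197 gene models elevated in YPD-media took 7.52% of its reads and between 0.506% and 0.715% in the other libraries. Their median fold over the next highest medium was 5.77, and 25 of them reached 1000 CPM. Of the 197, 10 lay under 1 CPM in each of the other 6 media. The 52 elevated in V8-media took 5.05% of its reads and at most 0.573% elsewhere, and 12 reached 1000 CPM. The 34 elevated in PDB-pH3 took 4.3% of its reads and at most 0.613% elsewhere. The direction of these shares follows from the rule that picked the gene models.

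The largest elevations were those of PKS02220.1 in YPD-media and PKR95237.1 in V8-media. PKS02220.1 lay at 2750 CPM in YPD-media and at 9.45 to 42.1 CPM in the other media, 65.3-fold above the next highest (counting interval 61.2 to 69.9). PKR95237.1 lay at 887 CPM in V8-media and at 15.1 CPM in the next highest, PDA-pH8, a ratio of 58.9 (52.7 to 65.9). The largest reductions were PKS00648.1 and PKS00647.1 in YPD-media. PKS00648.1 lay at 10.6 CPM there against 726 to 4820 CPM elsewhere, 68.2-fold below the next lowest medium (59.7 to 78.3). PKS00647.1 lay at 6.21 CPM against 424 to 2160 CPM, also 68.2-fold below the next lowest (57.3 to 81.8).

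These counts compare single libraries and have no replicate check; scaling by total reads gave 22 elevated in PDB-pH3, below 26 in Complete-media, and 6 lowered in PDB-pH3, and without YPD-media 91 were elevated in PDB-pH3 and 66 in V8-media, which turns their order, and 46, 14 and 4 were lowered in V8-media, PDB-pH3 and PDA-AP. With a pseudocount of 5 CPM, 11 were elevated in PDA-AP and 0 in Cornmeal-agar, and 48 were lowered in YPD-media, 11 in V8-media, 1 each in PDA-AP and PDA-pH8, and 0 in PDB-pH3 and Complete-media, and the log2 ratio of PKS00647.1 on the scale with the pseudocount went from -5.88 to -5.26.

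**Figure D2:**
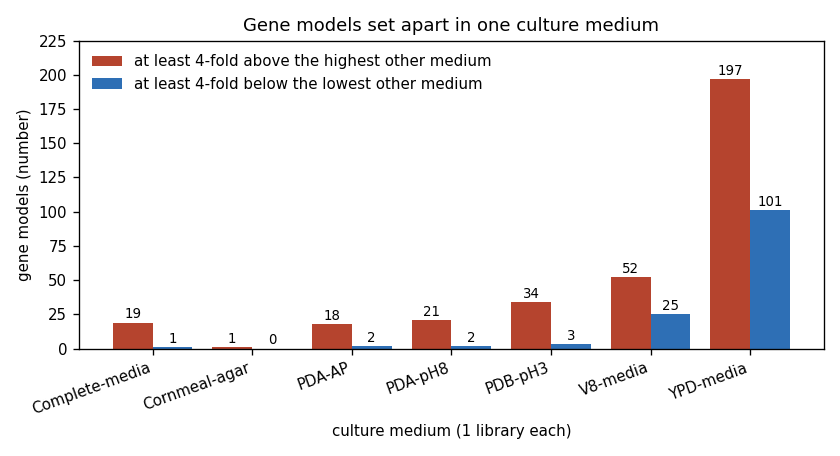
Bars give the number of gene models (vertical axis) at least 4-fold above the highest (red) or 4-fold below the lowest (blue) of the other 6 media, for each medium with 1 library (horizontal axis). YPD-media has 197 and 101, and the next medium, V8-media, has 52 and 25.

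PDB-pH3 and PDA-pH8 are the only cultures whose labels give a pH, 3 and 8, and they also differ in being broth and agar. Their comparison held 297 gene models at least 4-fold higher in PDB-pH3 and 289 at least 4-fold lower, or 586 in all. The 21 pairs of media ranged from 127 such gene models (Cornmeal-agar with PDA-AP) to 1587 (V8-media with YPD-media). The 297 higher gene models took 21.4% of the reads in PDB-pH3 and 3.46% in PDA-pH8, with a median fold of 6.76, and 43 of them differed 16-fold or more. The 289 lower gene models took 0.634% and 8.53%, with a median fold of 6.46, and 47 differed 16-fold or more. The direction of the shares follows from the 4-fold rule.

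For 189 of the 297 higher gene models PDB-pH3 was the highest of all 7 media, and for 94 PDA-pH8 was the lowest. Among the 289 lower gene models, PDB-pH3 was the lowest of the 7 for 118 and PDA-pH8 the highest for 163. PKR96580.1 was at 3390 CPM in PDB-pH3 and 13.8 CPM in PDA-pH8, a ratio of 247 (counting interval 220 to 278); it was at 1530 CPM in PDA-AP and 19.8 CPM in V8-media. PKR95836.1 was at 1360 and 8.5 CPM, a ratio of 160 (138 to 186), and at 1230 CPM in YPD-media. In the other direction, PKR97691.1 was at 5.05 CPM in PDB-pH3 and 1380 CPM in PDA-pH8, 272-fold lower (221 to 340). It was also low in PDA-AP (5.17 CPM) and YPD-media (3.9 CPM), and at 54.2 to 140 CPM in the remaining media. PKS02087.1 was at 2.52 and 786 CPM, 311-fold lower (232 to 429). It too was low in PDA-AP (1.66 CPM) and YPD-media (7.51 CPM), and at 26.5 to 194 CPM in the remaining media.

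The 586 ratios have no replicate check, and with a pseudocount of 5 CPM in place of 1 CPM the log2 ratio of PKR97691.1 went from -7.83 to -7.1, that of PKS02087.1 from -7.8 to -6.72, and the lower gene models numbered 176. With scaling by total reads the median gene of PDB-pH3 lay at -0.335 (log2) relative to the other media, against 0.0512 with TMM, and there were 222 higher and 426 lower gene models, so that 34.3% of calls were higher in place of 50.7%.

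PDA-AP and PDA-pH8 share the PDA base in their labels. Here 289 gene models were at least 4-fold higher and 221 at least 4-fold lower in PDA-AP. The higher ones took 14.0% of the reads in PDA-AP and 1.46% in PDA-pH8, with a median fold of 7.48, and 68 differed 16-fold or more. The lower ones took 1.22% and 10.4%, with a median fold of 6.87, and 42 differed 16-fold or more. Again the direction of the shares follows from the 4-fold rule. PDA-AP was the highest of all 7 media for 168 of the 289, and PDA-pH8 was the highest of the 7 for 135 of the 221.

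PKS00610.1 was at 1210 CPM in PDA-AP and 3.52 CPM in PDA-pH8, a ratio of 345 (counting interval 275 to 439). It was also high in Cornmeal-agar (1110 CPM) and Complete-media (260 CPM) and at 1.13 to 7.22 CPM in the remaining media. PKR94839.1 was highest in the same 3 media, at 212 CPM in PDA-AP, 91.6 CPM in Cornmeal-agar and 56.3 CPM in Complete-media. Only 3 of its reads were counted in PDA-pH8 (0.141 CPM), which gave a ratio of 1510 with an interval of 515 to 7310. PKS02087.1 was 473-fold lower in PDA-AP (1.66 against 786 CPM, 342 to 676). PKR99155.1 was 256-fold lower (7.52 against 1930 CPM, 220 to 301), and it reached 21900 CPM in PDB-pH3 and 2210 CPM in YPD-media.

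The 510 ratios have no replicate check either, and with a pseudocount of 5 CPM the higher gene models numbered 192 and the log2 ratios of PKS00610.1, PKR94839.1 and PKS02087.1 went from 8.07, 7.55 and -8.21 to 7.16, 5.4 and -6.89. Both pair comparisons use the same PDA-pH8 library, so any chance value in it would enter both. The PDA-pH8 value of PKS02087.1 enters both of its ratios, and whether it is a chance value was not tested.

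**Figure D3:**
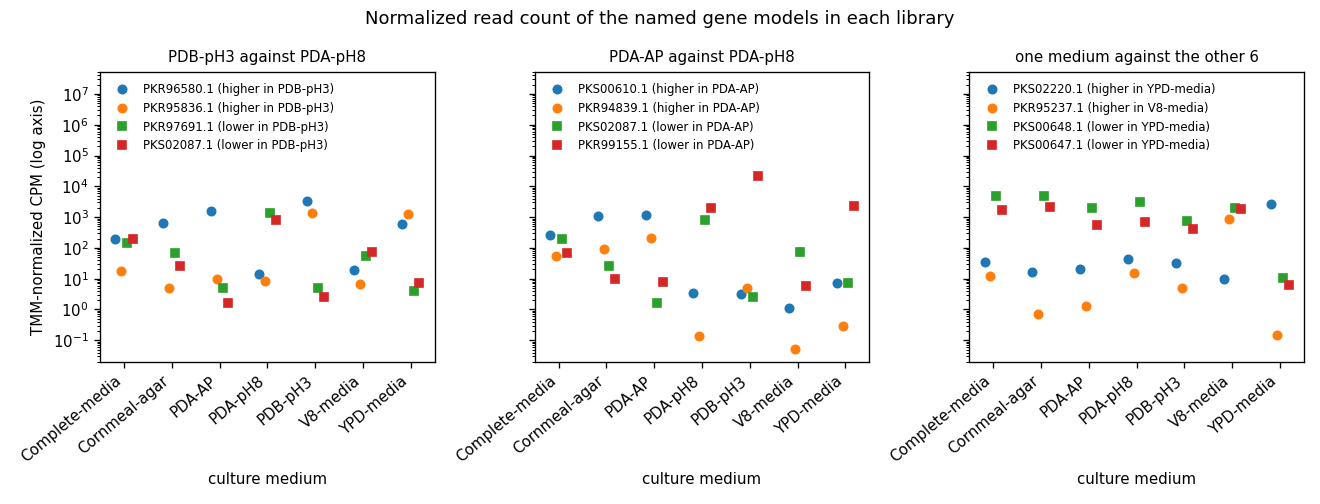
TMM-normalised read count (CPM, log axis) of the named gene models in each of the 7 media (horizontal axis), 1 point per library, in a panel for each kind of comparison, with circles for gene models higher and squares for those lower in the medium named in the key. PKS02220.1 lies at 2750 CPM in YPD-media and at no more than 42.1 CPM elsewhere, and PKR99155.1 spans 5.61 CPM in V8-media to 21900 CPM in PDB-pH3.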

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

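Leaving out YPD-media was the only alternative chosen after seeing the data. Recomputed were the numbers detected, elevated and lowered, the counts of the 2 pair comparisons described, the shares of reads in the top 10 and top 100, the named ratios and the rho of 5 of the 21 pairs of media, each under the alternatives that concern it. Other values, such as the coverage by sets of media, the gene models missed in a single medium, the shares of reads held by elevated or pair-called gene models, the principal components and the ranges over media, were not. Values for the 7 media follow the order Complete-media, Cornmeal-agar, PDA-AP, PDA-pH8, PDB-pH3, V8-media and YPD-media. Detection ranged from 8349 to 9281 gene models in all 7 media and from 9309 to 9542 in at least 1, counts too close to the 10130 gene models to rise by 1.5 times. With a minimum of 1 read, 261 were detected in 1 to 6 media and 16 in exactly 1; with a minimum of 1 CPM these were 960 and 134. YPD-media kept the highest number elevated and lowered under every alternative that included it. Median-of-ratios factors and a minimum of 200 reads left all elevated, lowered and pair counts within 1.5 times. Dropping the minimum could not change them, since 4-fold on the CPM + 1 scale already needs more than 50 reads at these depths. Scaling by total reads gave 22 elevated in PDB-pH3, below 26 in Complete-media, and 6 lowered in PDB-pH3. With it the median gene lay at 0.155, 0.152, -0.335 and -0.196 (log2) relative to the other media in Complete-media, Cornmeal-agar, PDB-pH3 and V8-media, against -0.0256, -0.00727, 0.0512 and 0.0479 with TMM. A pseudocount of 5 CPM gave 0 elevated in Cornmeal-agar, 11 in PDA-AP, and 0, 1, 1, 0, 11 and 48 lowered in Complete-media, PDA-AP, PDA-pH8, PDB-pH3, V8-media and YPD-media, with 176 lower in PDB-pH3 than in PDA-pH8 and 192 higher in PDA-AP than in PDA-pH8. At 2-fold, 113, 18, 79, 68, 170, 248 and 796 gene models were elevated and 2, 2, 17, 23, 64, 140 and 818 lowered; 992 were higher and 1079 lower for PDB-pH3 against PDA-pH8, and 877 and 694 for PDA-AP against PDA-pH8. At 8-fold, 5, 0, 3, 6, 7, 16 and 58 were elevated and 0, 0, 1, 0, 0, 7 and 20 lowered, with 119 and 108, and 135 and 93, for the pairs. Against the median of the other media, 202, 125, 207, 152, 263, 190 and 595 were elevated and 22, 22, 48, 59, 91, 195 and 508 lowered, so that V8-media came after PDB-pH3, PDA-AP and Complete-media among the elevated. These thresholds change the counts by construction. Leaving out YPD-media gave 91 elevated in PDB-pH3, above 66 in V8-media, and 4, 14 and 46 lowered in PDA-AP, PDB-pH3 and V8-media; fewer media to exceed raises such counts by construction, and leaving out the other media singly was not run. Without each library's most abundant gene, the top 10 held 6.83, 7.85, 9.23, 6.88, 10.5, 8.08 and 6.31% of reads and the top 100 held 23.8, 24.4, 27.6, 26.1, 32.0, 29.8 and 22.9%. With at least 10 reads in every library, rho was 0.959 for Cornmeal-agar with PDA-AP, 0.737 for Complete-media with YPD-media, 0.816 for PDB-pH3 with YPD-media, 0.873 for PDA-pH8 with PDB-pH3 and 0.881 for PDA-AP with PDA-pH8; Pearson r for PDB-pH3 with YPD-media was 0.853. The 12 named ratios, at 55.3 or more on the CPM + 1 scale, kept their direction in their 36 alternatives; with a pseudocount of 5 CPM, which lowers ratios with a low side by construction, those of PKR94839.1 (5.4 on the log2 scale), PKS02087.1 (-6.89 and -6.72), PKS00610.1 (7.16), PKR97691.1 (-7.1) and PKS00647.1 (-5.26) moved by over 1.5 times. The lists of genes by pathway were not run, because the identifiers could not be matched to names. With 1 library per medium no replicate could be left out. Apart from changes that follow from a setting's construction, the cause was not tested.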

Other observations

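The sets of media, the scaling comparison, the comparison of library totals, the runs of identifiers and the test of shared reads on consecutive identifiers were chosen after the values had been seen. Some gene models were elevated together in several media. Of the 21 pairs of media, PDB-pH3 with YPD-media held the most gene models at least 4-fold above all other 5 media (22, at a median of 182 CPM against 10.5 CPM elsewhere). Cornmeal-agar with PDA-AP followed with 17 (248 against 8.47 CPM) and Complete-media with PDA-pH8 with 11 (528 against 11.7 CPM). Of the 35 sets of 3, Complete-media, Cornmeal-agar and PDA-AP held 19, at a median of 108 CPM against 0.904 CPM in the remaining media, and no other set of 3 held more than 4.

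YPD-media held more gene models set apart than any other medium. In YPD-media the 10 most abundant gene models held 6.93% of the reads and the 100 most abundant 23.71%, the lowest shares of the 7 libraries. These shares argue against a few abundant genes taking most of the reads. Leaving out the 270 gene models in any library's top 100 left 181 elevated in YPD-media against at most 44 elsewhere. Only 25 of the 197 elevated in YPD-media reached 1000 CPM, so this count had little room to fall and decides nothing further. The YPD-media total of reads was 1.01 times the median of the other 6 and within their range, which argues against depth. Over 3 scalings and both directions, the YPD-media count was at least 2.47 times the next highest, which argues against scaling between libraries. Variation between cultures of one medium remains open and cannot be told apart from the medium with 1 library per medium. The same holds for growth in liquid or on plates, harvest and library preparation. The biological difference between the media was not tested.

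Gene models with consecutive identifiers were, on average, weakly correlated across the media. The mean Pearson correlation of their 7 values was 0.0935 over 8792 pairs, above the highest of 1000 shuffled orders (0.0207), which argues against random placement. This mean was not recomputed without YPD-media. At 2 to 5 identifiers apart the mean was 0.0179, above the highest of the shuffled orders (0.00946). That mean rests on 2 steps (0.0311, highest of the shuffled orders 0.0171) and less on 3 (0.0172 and 0.0157), while 4 (0.00954) and 5 steps (0.0138) lay within the shuffled orders (highest 0.0171 and 0.0162). For consecutive identifiers, reads shared between overlapping neighbours cannot be told apart from joint regulation without gene positions and strand. The same holds at 2 steps, since a gene model that overlaps both its neighbours could link them. The test at 2 to 5 steps therefore does not decide on shared reads. A hypothesis is that identifier order follows the contigs and that neighbouring genes may be regulated together; duplicated genes that share reads were not tested. A run of 3 consecutive identifiers that includes PKS00647.1 and PKS00648.1, picked after seeing the values, was lowered in YPD-media, as was another run of 3. The set lowered in YPD-media held 6 consecutive pairs, above the mean of its random sets (1.07) but below their highest value (8).

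The 588 gene models with no read in any library do not appear to be a matter of depth. Dividing the depth of every library by 2 raised their number to 599, a rise of 1.87%, which argues against too few reads. They held 75 pairs of consecutive identifiers, against a mean of 34.3 and a highest value of 51 in 1000 random sets of the same size, and their longest run was 5 identifiers. Whether they are silent in culture, are duplicated sequence whose reads were left unassigned, or are wrong models was not tested.

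In YPD-media, 11 consecutive pairs were found among the 197 elevated gene models (mean of 1000 random sets matched on expression 3.75, highest 10) and 6 among the 101 lowered ones (mean of the random sets 1.07, highest 8). Sets elevated or lowered in the other media, and sets elevated in several media, were examined only where they held at least 10 gene models. Among the lowered sets of the other media, only that of V8-media was this large. None of the sets examined went above the highest of its random sets. For small sets this says little. The set elevated in PDA-AP held 1 pair, with a mean of 0.033 and a highest value of 1 in its random sets. The set elevated in Complete-media, Cornmeal-agar and PDA-AP also held 1 pair (mean 0.029, highest 1).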
